A study of Homo sapiens with 2 samples.

How the data were processed

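Gene expression was measured in MCF-7 cells after transfection with CLOCK siRNA or mock siRNA, in 2 dual-label Agilent arrays. Per the labels, each array carried Cy5-labelled RNA from CLOCK siRNA cells and Cy3-labelled RNA from mock siRNA cells, with the same dye order on both. The series design text calls the arrays biological replicates. Each array is itself a pair of CLOCK siRNA and mock siRNA RNA, so the samples form a single group of 2 ratios and no further pairing applies.

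The deposited value table holds log ratios of the 2 channels for 43376 spots per array, taken here as log10 ratios. Agilent Feature Extraction is named in the submitters' processing notes, with no version, and base 10 is the base of that program's log ratio. Neither the base nor the background correction and dye normalization are given in the sources used here, and no scanner intensities were used, so signal over background is unknown for each spot. Direction was taken from the dyes in the labels, as Cy5 over Cy3, and CLOCK itself was lower in that direction. Both deposited columns have a median of 0. They span -0.916 to 1.37 on array 1 and -0.986 to 1.39 on array 2 on the log10 scale. Values were multiplied to the log2 scale and otherwise used as deposited, and the gene-level median was then -0.02 on array 1 and -0.03 on array 2.

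Exact zeros needed a decision. They made up 22.1% of values on array 1 (9574) and 22.5% on array 2 (9773), while rounding of a continuous ratio would give about 1.43 and 1.40. A total of 8796 spots were at 0 on both arrays and 1755 on 1 array only. Zeros on both arrays filled 54.3% of spots of genes expected to be silent in breast epithelium, 1.89% of spots of luminal markers and 16.1% of all spots with a single symbol. Exact zeros were therefore taken as spots without a ratio and left out. This was decided before any test was run but after the values were seen, and the test design fixed earlier did not mention zeros. Keeping zeros as values is an added alternative, under which limma called 0 genes. A further 16 values were missing on array 1 and 36 on array 2.

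Probes were named through the platform's annotation table, with symbols updated by Entrez gene identifier or accession against a RefSeq gene table of assembly GRCh38.p14, used for names alone. A single symbol was found for 31332 spots, of which 31291 matched by Entrez identifier, 11 by accession and 30 kept the annotation's own symbol. No symbol was found for 11951 spots and several for 93, and these were not named. Of 18312 genes, 3717 had every spot at 0 on 1 or both arrays and were not tested. In the deposited table, repeated spots mostly carry an identical value: of 209 accessions with at least 10 spots, 201 hold 1 value throughout. Identical values within a gene were counted once and distinct values averaged. Distinct values existed for 2279 genes, including 394 of the changed genes, and in 37 of these the separate values differed in direction.

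The test was limma 3.58.1 in R 4.3.3, an intercept-only linear model of the log2 ratios with empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment over 14595 genes and a threshold of 0.05. With 2 arrays the fit has 1 residual degree of freedom per gene, to which moderation added 1.90, so p-values rest on the spread between these 2 arrays and on the spread shared across genes. The median SD between arrays was 0.0744 on the log2 scale. Errors are given as SD between the 2 arrays.

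Before the data were examined, 27 gene lists were fixed: core clock and clock output genes, oestrogen receptor targets, luminal, basal, mesenchymal, leukocyte and endothelial markers, S phase, G2 and M phase and histone genes, p53, interferon, NF-kB, immediate early and aryl hydrocarbon receptor genes, endoplasmic reticulum stress, heat shock, hypoxia, cholesterol, fatty acid and oxidative phosphorylation genes, DNA repair genes, apoptosis regulators, RNA interference machinery, ribosomal proteins and genes expected to be silent in breast epithelium. Some members stand in 2 lists. Lists were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. At a preset correlation camera's p-value takes genes as its units. The spread between the 2 arrays enters only through the statistic of each gene. Camera with an estimated correlation, camera on ranks and fry were alternatives. With an estimated correlation, which rests on 1 residual degree of freedom, 0 of the 27 lists passed, and with fry, which tests a list against no change and not against other genes, 0 passed as well.

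Named genes also followed a rule fixed in advance. It took CLOCK, then for each direction the 12 changed genes ranked by the smaller of their 2 absolute ratios, then up to 4 changed members of each list in the same ranking, and the core clock genes. Alternatives covered centring and scaling of arrays, robust, absent or pooled variance moderation, each probe or a median per gene, a minimum change of 1.2-fold, an adjusted p under 0.10, and each array alone. Handling of zeros and the base of the logarithm were alternatives added after seeing the data.

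The test was tried on simulated data of 14595 genes, with each variance drawn from the distribution that limma fitted to the real arrays. Errors were independent between genes and unchanged genes had no shift, so these data met the test's assumptions. They cannot show the error rate on the real arrays. With 200 genes changed by 1.5-, 2- or 3-fold, 0 were called at any size. With 3000 changed genes, 80% were called at 1.5-fold, 92.5% at 2-fold and 97.3% at 3-fold, and 118 of 2816 calls were unchanged genes. In these simulations the test called genes only where many changed. A simulated list shifted by 0.50 or 2.0 on the log2 scale was called by camera with its preset correlation, and none of the other lists was. Camera with an estimated correlation and fry called the shifted list at neither size. In that simulation only 1 of 27 lists was shifted and its genes were independent. It therefore cannot settle how firm a call lost in those tests was.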

Results

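MCF-7 cells, an established human breast cancer line that expresses the oestrogen receptor, were transfected with an siRNA directed against CLOCK or with a mock siRNA. The question, as the labels put it, was how expression after CLOCK siRNA stood relative to that negative control. Total RNA of both kinds was hybridised together on each of 2 dual-label Agilent arrays. RNA from cells given CLOCK siRNA carried Cy5 and RNA from cells given mock siRNA carried Cy3 on both arrays. Every value is therefore a ratio of CLOCK siRNA over mock siRNA, and 0 on the log2 scale means equal signal in both. Of 18312 genes with a symbol, 14595 had a ratio on both arrays. The number of arrays limits the precision of every value. Dyes were not swapped, so a dye effect on a gene would enter its ratio in full.

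CLOCK itself, the transcription factor that pairs with BMAL1 to drive the circadian clock, was lower on both arrays. Its log2 ratio was -2.64 on array 1 and -2.82 on array 2, with a mean of -2.73 ± 0.13 (SD, n = 2, limma adjusted p = 0.0324). CLOCK RNA after CLOCK siRNA thus stood at 15.0% of the mock level, 6.65-fold lower. The value table holds 2 distinct values for CLOCK, at 12.4% and 18.2% of mock. Without variance moderation the adjusted p of CLOCK was 0.253, and with exact zeros kept as values it was 0.0810. It ran from 0.0322 to 0.253 over the settings in which CLOCK was followed. Those did not include, among others, pooled SD, single probes, and fits without silent genes or without genes with any spot at 0. These sizes take the deposited logarithms as base 10, which the value table does not state. Read as base 2, the fold for CLOCK would be 1.77, while the sign and the test of each gene stay as they are.

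With the target included, 2953 of the 14595 measured genes differed between CLOCK siRNA and mock siRNA in limma at a Benjamini-Hochberg adjusted p under 0.05. Of these, 1192 genes were higher and 1761 were lower, so 59.6% of the changed genes were lower. Most changes were modest, with a median absolute log2 ratio of 0.58 among the changed genes. A change of at least 2-fold was found in 462 of them, 198 higher and 264 lower. By size alone, 1358 genes moved at least 1.5-fold in the same direction on both arrays, 573 up and 785 down, against 37 that moved as far in opposite directions. The log2 ratios of the 2 arrays correlated across genes with Pearson r = 0.754 and Spearman rho = 0.791, a description across genes, which are not replicates. The count of changed genes depended on how spread was modelled. It was 1 without variance moderation and 0 in limma when exact zeros were kept as values, where 5562 genes had an unadjusted p under 0.05, against 6466 with zeros left out.

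**Figure D1:**
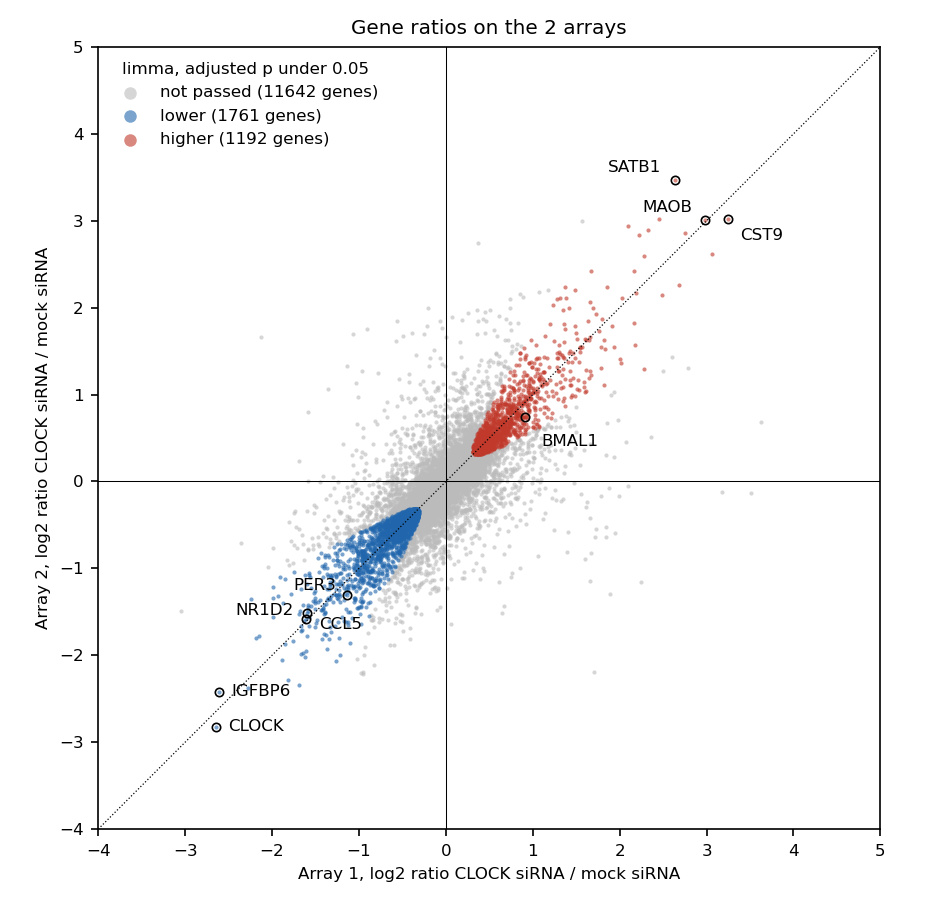
Log2 ratio of CLOCK siRNA over mock siRNA for each of 14595 genes on array 1 (horizontal axis) and array 2 (vertical axis), with genes higher (1192, red), lower (1761, blue) or not passed (11642, grey) in limma, and the dotted line marking equal ratios. CLOCK lies at -2.64 and -2.82, at the lower left end of the genes, and SATB1, MAOB and CST9 lie at the upper right.

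The higher genes with the largest ratios held on both arrays spanned several functions. CST9, a cystatin family gene, had a mean log2 ratio of 3.13 ± 0.16 (SD, n = 2), which is 8.77-fold. MAOB, the mitochondrial monoamine oxidase B, rose 7.96-fold (log2 2.99 ± 0.02), and VEGFC, a growth factor for lymphatic vessels, rose 6.99-fold (log2 2.81 ± 0.08). SATB1, a chromatin organiser, rose 8.29-fold, with a wider spread (log2 3.05 ± 0.59). ANKRD22 (log2 2.84), CSGALNACT1, an enzyme of chondroitin sulfate synthesis (log2 2.74), and CST9L, another cystatin family gene (log2 2.61), followed. DOCK10, an activator of Rho family GTPases, had a log2 ratio of 2.44. ANXA1, a phospholipid-binding annexin, stood at 2.48, the matrix protein gene THBS4 at 2.53, the cadherin gene CDH18 at 2.18 and the prolyl isomerase gene FKBP7 at 2.30. Each of these 12 had an adjusted p of 0.0324 in limma, the lowest that any gene reached. CST9 and CST9L are paralogs, so cross-hybridisation leaves the share of each uncertain. DOCK10 and ANXA1 also had spots at exactly 0, which were not used. With zeros kept as values their log2 ratios were 1.22 and 1.24.

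After CLOCK itself, the lower genes with the largest ratios held on both arrays began with IGFBP6, a binding protein for insulin-like growth factors. It fell 5.72-fold, with a mean log2 ratio of -2.52 ± 0.13 (SD, n = 2). PRTN3, a protease best known from neutrophils, fell 5.01-fold (log2 -2.32 ± 0.07). RND2, a Rho family GTPase, fell 4.15-fold (log2 -2.05 ± 0.33), and ADAM19, a membrane metalloprotease, 3.91-fold (log2 -1.97 ± 0.26). The long noncoding RNA LINC01480 had a log2 ratio of -1.99, AMBP, the precursor of alpha-1-microglobulin and bikunin, -2.02, and SPNS3 -1.80. The lens crystallin gene CRYBA2 stood at -1.83 and the phosphodiesterase gene PDE1B at -1.69. The adjusted p in limma was 0.0353 for AMBP and 0.0324 for the others. Among the same genes, RASA4CP (log2 -1.97) is a pseudogene and CGB3 (log2 -1.86) belongs to the family of near-identical chorionic gonadotropin beta genes, so both are uncertain.

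Genes of the circadian clock moved apart. Among 15 measured core clock genes other than CLOCK, 3 were higher, 3 were lower and 9 did not pass. NR1D2, which encodes the repressor REV-ERB beta, fell to 33.0% of mock (log2 -1.60 ± 0.02, SD, n = 2, limma adjusted p = 0.0324), from 2 distinct values at -2.02 and -1.18. PER3, a period gene, fell with a log2 ratio of -1.22 ± 0.12, and NR1D1, which encodes REV-ERB alpha, with -0.51 ± 0.06. In the opposite direction, BMAL1, the partner of CLOCK, rose 1.77-fold (log2 0.83 ± 0.11). The repressor gene CRY1 rose 1.63-fold (log2 0.70 ± 0.04), and RORA, an activator of BMAL1 transcription, had a log2 ratio of 0.57 ± 0.13, or 0.29 with zeros kept as values. NPAS2, a paralog of CLOCK, had a log2 ratio of 0.46 ± 0.30 and did not pass (adjusted p = 0.104 in limma). PER1 at -0.26, PER2 at 0.12, CRY2 at 0.13, BMAL2 at 0.19, the casein kinase genes CSNK1E at -0.25 and CSNK1D at -0.05, BTRC at -0.02 and TIMELESS at 0.01 did not pass either. As a set these core genes did not shift against all other genes (camera adjusted p = 0.741, 3 higher and 3 lower when adjusted over the list alone). Camera's direction was higher and the list's median was 0.01, while its mean was -0.06.

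**Figure D2:**
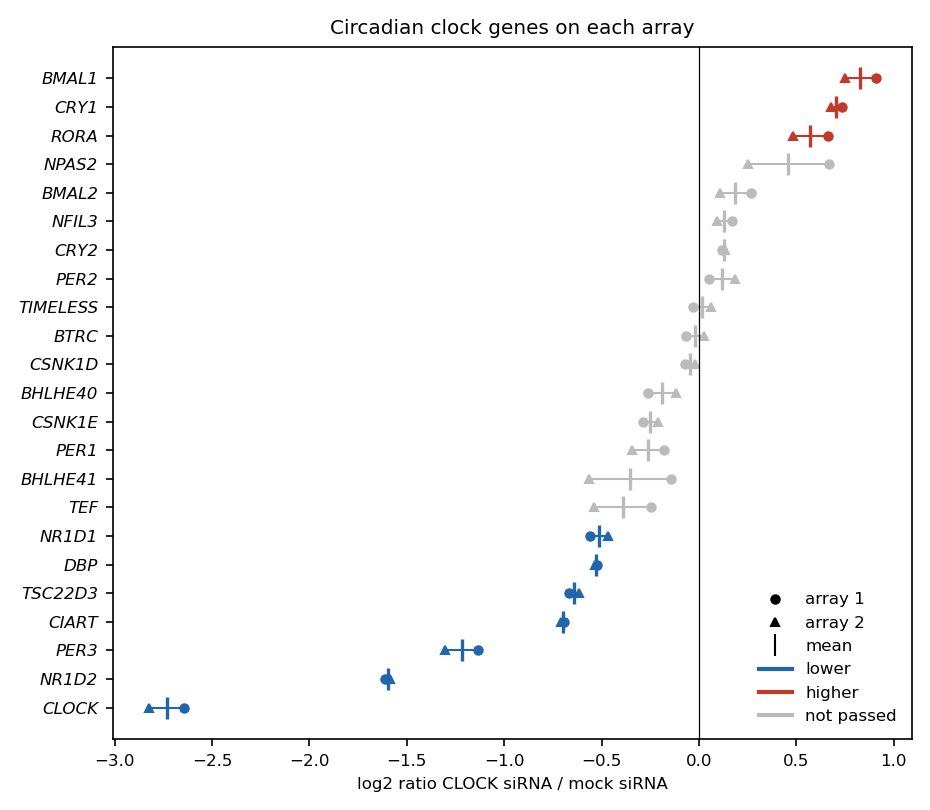
Log2 ratio of CLOCK siRNA over mock siRNA (horizontal axis) of CLOCK, the other core clock genes and further clock outputs, with array 1 as a circle, array 2 as a triangle and their mean as a bar, coloured by the limma call. NR1D2, PER3, CIART, TSC22D3, DBP and NR1D1 were lower, BMAL1, CRY1 and RORA were higher, and the remaining genes besides CLOCK, in grey, did not pass. Some of the 19 measured output genes are not drawn, and those did not pass. In the whole output list, 12 genes lay below 0 and 7 above.

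Direct outputs of the clock were lower more often than higher. Of 19 measured output genes, a list that shares the period, cryptochrome and REV-ERB genes with the core list, 6 were lower, 1 was higher and 12 did not pass. Besides NR1D2 and PER3, CIART, a clock repressor gene, fell to 61.6% of mock (log2 -0.70 ± 0.01, SD, n = 2, limma adjusted p = 0.0324). The single higher member was CRY1. The list median was -0.21, and the list did not pass against all other genes (camera adjusted p = 0.225, 6 lower and 1 higher when adjusted over the list alone).

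Type I interferon response genes were lower as a group. All 37 measured members had a mean log2 ratio below 0, 27 were lower, none was higher and 10 did not pass. CCL5, a chemokine gene, fell to 34.1% of mock (log2 -1.55 ± 0.06, SD, n = 2). OASL had a log2 ratio of -1.43 ± 0.06 and OAS2 of -1.34 ± 0.02, both of the oligoadenylate synthetase family, and IFIT2, an RNA-binding antiviral gene, of -1.28 ± 0.02. The list median was -0.73 on array 1, -0.53 on array 2 and -0.59 over gene means, beside -0.26 for genes expected to be silent in breast epithelium. Camera gave an adjusted p of 6.1e-11 with its preset correlation, and 33 members were lower when adjusted over the list alone. That camera p-value takes genes, not arrays, as its units. The call was lost with the correlation estimated from the 2 arrays (adjusted p = 0.844 with an estimated correlation).

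Proliferation genes were lower in both phase lists. In the G2 and M phase list, 10 of 29 measured genes were lower, none was higher and 19 did not pass, with a list median of -0.26. The mitotic kinase gene AURKA had a log2 ratio of -0.62 ± 0.03 (SD, n = 2), its activator TPX2 -0.55 ± 0.04, the phosphatase gene CDC25C -0.55 ± 0.07 and the kinesin gene KIF23 -0.47 ± 0.09. Camera gave this list an adjusted p of 8.69e-05, with 20 members lower when adjusted over the list alone (adjusted p = 0.844 with an estimated correlation). Among 29 measured S phase and DNA replication genes, 8 were lower, none was higher and 21 did not pass, with a list median of -0.24. MCM7, a subunit of the replicative helicase, had a log2 ratio of -0.61 ± 0.01, the ribonucleotide reductase gene RRM2 -0.55 ± 0.05, the replication factor gene MCM10 -0.53 ± 0.05 and the thymidine kinase gene TK1 -0.47 ± 0.05. The S phase list had a camera adjusted p of 0.000714 and 11 lower members when adjusted over the list alone (adjusted p = 0.844 with an estimated correlation). Replication-dependent histone genes did not pass as a list (22 measured, camera adjusted p = 0.741). Among them H2AC4 at -0.53 and H2BC21 at -0.43 were lower, H4C3 at 0.48 and H2BC12 at 0.34 were higher, and 18 did not pass. When adjusted over the list alone, 2 histone genes were lower and 1 was higher. The proliferation medians lay close to that of genes expected to be silent in breast epithelium, which was -0.26.

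Hypoxia response genes were lower as a list, and 7 of 22 measured members were lower, none higher, with 15 not passing. The glycolytic aldolase gene ALDOC fell to 37.7% of mock (log2 -1.41 ± 0.02, SD, n = 2), and NDRG1, a hypoxia-induced stress gene, to 51.2% (log2 -0.97 ± 0.08). PFKFB4, a regulator of glycolysis, stood at -0.54 ± 0.03 and BNIP3, a mitophagy receptor gene, at -0.48 ± 0.01. The list median was -0.27, again close to the -0.26 of the genes expected to be silent. Camera gave an adjusted p of 0.00145, and 13 members were lower when adjusted over the list alone (adjusted p = 0.844 with an estimated correlation).

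Cytosolic ribosomal protein genes were the only list of the 27 that passed camera with its preset correlation and direction higher. Of 33 measured members, 9 were higher, none was lower and 24 did not pass. RPLP2 had a log2 ratio of 0.91 ± 0.11 (SD, n = 2), RPS20 of 0.76 ± 0.06, RPS27 of 0.68 ± 0.14 and RPL38 of 0.59 ± 0.04. The list median was 0.28 on array 1 and 0.30 on array 2. Camera gave an adjusted p of 6.61e-06, with 15 higher and 1 lower when adjusted over the list alone (adjusted p = 0.844 with an estimated correlation). Genes with many processed pseudogenes, such as these, are open to cross-hybridisation. The later search of families by the letters of their symbols used another test, of counts of changed genes, and other sets of genes. In it neither RPL nor RPS passed. Of 58 RPL genes, 6 were higher and 4 lower, with a median of 0.18 (Fisher's exact test for higher, adjusted p = 0.952). Of 43 RPS genes, 9 were higher and 1 lower, with a median of 0.19 (adjusted p = 0.240).

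**Figure D3:**
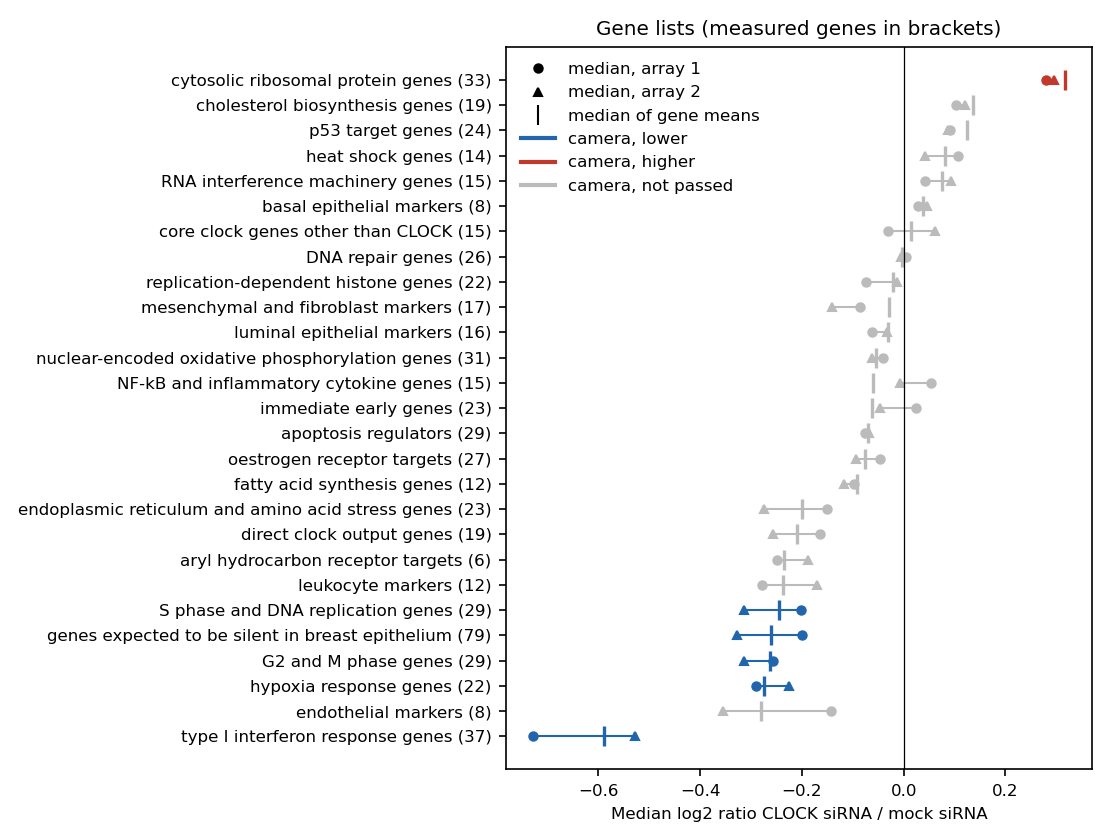
Median log2 ratio of CLOCK siRNA over mock siRNA (horizontal axis) of 27 gene lists, with the number of measured genes in brackets, array 1 as a circle, array 2 as a triangle and the median of gene means as a bar, coloured by camera with its preset correlation. Type I interferon response genes lie lowest at -0.59 and cytosolic ribosomal protein genes highest at 0.32.

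Genes expected to be silent in breast epithelium, mainly olfactory receptor, taste receptor, hair keratin-associated and lens crystallin genes, were also lower as a list. Only 79 of the 221 on the array had a ratio on both arrays. Of those, 23 were lower, 7 were higher and 49 did not pass, with a median of -0.26 over gene means, -0.20 on array 1 and -0.33 on array 2. The olfactory receptor genes OR11G2 (log2 -1.51 ± 0.10, SD, n = 2) and OR1L3 (-1.46 ± 0.11) were lower. OR2A20P (1.18 ± 0.17), a pseudogene, and OR51B4 (1.79 ± 0.70) were higher. Camera gave the list an adjusted p of 0.0139, with 28 lower and 9 higher when adjusted over the list alone (adjusted p = 0.844 with an estimated correlation). The call was also lost when exact zeros were kept as values (adjusted p = 0.504).

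Markers of other cell types moved in both directions, except that no endothelial marker passed as higher over all genes. No such list passed. Only 12 of 23 leukocyte and 8 of 13 endothelial markers on the array had a ratio on both arrays. Their list medians of -0.24 and -0.28 lay near the -0.26 of genes expected to be silent in breast epithelium. Of 12 measured leukocyte markers, 4 were lower and 1 was higher (camera adjusted p = 0.411, the same counts when adjusted over the list alone). The integrin gene ITGAM stood at 0.97 ± 0.12 (SD, n = 2), the lipopolysaccharide co-receptor gene CD14 at -0.84 ± 0.09, LAPTM5 at -0.63 ± 0.19, or -0.32 with zeros kept as values, and NKG7 at -0.48 ± 0.04. Of 8 endothelial markers, 2 were lower, ROBO4 at -0.94 ± 0.26 and the von Willebrand factor gene VWF at -0.49 ± 0.04 (camera adjusted p = 0.641, 3 lower and 1 higher when adjusted over the list alone). Of 17 mesenchymal and fibroblast markers, 2 were higher and 3 lower (camera adjusted p = 0.741, 2 higher and 4 lower when adjusted over the list alone). Smooth muscle actin gene ACTA2 stood at 0.80 ± 0.02, the repressor gene ZEB2 at 0.76 ± 0.22 (0.51 with zeros kept as values), the fibrillin gene FBN1 at -0.68 ± 0.01 and THY1 at -0.46 ± 0.02. Of 8 basal epithelial markers, the caveolin gene CAV1 at 1.00 ± 0.05 and the laminin gene LAMB3 at 0.50 ± 0.06 were higher and the keratin gene KRT15 at -0.73 ± 0.04 was lower (camera adjusted p = 0.701, 3 higher and 2 lower when adjusted over the list alone).

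Luminal epithelial markers and oestrogen receptor targets did not pass as lists. Of 16 luminal markers, 4 were lower, none was higher and 12 did not pass (camera adjusted p = 0.741). These 4 were the epithelial transcription factor genes ELF3 at -0.81 ± 0.02 (SD, n = 2) and SPDEF at -0.46 ± 0.07, the mucin gene MUC1 at -0.63 ± 0.0029 and the claudin gene CLDN4 at -0.43 ± 0.10. When adjusted over the list alone, 4 luminal markers were lower and 2 were higher. Of 27 oestrogen receptor targets, 7 were lower, 1 was higher and 19 did not pass (camera adjusted p = 0.713, 8 lower and 6 higher when adjusted over the list alone). Lower targets included KRT13, a keratin gene, at -0.94 ± 0.03, the scaffold gene PDZK1 at -0.86 ± 0.07 and the carbonic anhydrase gene CA12 at -0.62 ± 0.01. The chemokine gene CXCL12 was higher at 0.57 ± 0.10.

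Stress and damage lists did not pass either, though single members changed. Among 24 p53 targets, 5 were higher and 1 was lower (camera adjusted p = 0.123, 6 higher and 1 lower when adjusted over the list alone). The sestrin gene SESN1 stood at 0.97 ± 0.01 (SD, n = 2), SPATA18 at 0.79 ± 0.06, TP53INP1 at 0.69 ± 0.05 and the metabolic phosphatase gene TIGAR at 0.49 ± 0.03. Among 23 genes of endoplasmic reticulum and amino acid stress, 4 were lower and 1 was higher (camera adjusted p = 0.276, 9 lower and 1 higher when adjusted over the list alone). PDIA4, a protein disulfide isomerase gene, stood at 0.50 ± 0.11, the pseudokinase gene TRIB3 at -0.42 ± 0.02, PHGDH of serine synthesis at -0.45 ± 0.06 and VLDLR at -0.35 ± 0.0011. Of 14 heat shock genes, the chaperone genes HSP90AA1 at 0.74 ± 0.01 and HSPE1 at 0.45 ± 0.08 were higher and BAG3 at -0.44 ± 0.01 was lower (camera adjusted p = 0.380, the same counts when adjusted over the list alone).

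In 26 DNA repair genes, ERCC5 of nucleotide excision repair at 0.66 ± 0.01 (SD, n = 2) was higher and XRCC3 of recombination at -0.36 ± 0.05 was lower (camera adjusted p = 0.668, 1 higher and none lower when adjusted over the list alone). Camera's direction for these was higher and their mean 0.03, while the median lay just below 0. Among 29 apoptosis regulators, the survival gene MCL1 at 0.51 ± 0.05 was higher. The pro-apoptotic genes BMF at -0.46 ± 0.03 and HRK at -0.38 ± 0.03 and the death receptor gene TNFRSF10B at -0.49 ± 0.11 were lower (camera adjusted p = 0.668). None of these regulators passed when adjusted over the list alone.

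Signalling lists were mixed. In 15 measured NF-kB and inflammatory cytokine genes, the cytokine gene TNF at -0.85 ± 0.01 (SD, n = 2) and TNFAIP2 at -0.79 ± 0.07 were lower, and TNFAIP3, an inhibitor of NF-kB, at 1.00 ± 0.37 and the adhesion gene ICAM1 at 0.44 ± 0.00099 were higher. Camera gave an adjusted p of 0.960 with direction higher, while the list's median of -0.06 and mean of -0.07 were below 0. By array, its median was 0.05 on array 1 and -0.01 on array 2. Of these genes, 4 were higher and 5 lower when adjusted over the list alone. Among 23 immediate early genes, 5 were higher and 2 were lower (camera adjusted p = 0.741, the same counts when adjusted over the list alone). SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, rose 3.07-fold (log2 1.62 ± 0.0041), and the phosphatase gene DUSP6, which acts on ERK, stood at 0.63 ± 0.13. The nuclear receptor gene NR4A2 stood at 0.59 ± 0.05 and IER3 at -0.65 ± 0.04. The median of this list was -0.06, while its mean of 0.03 and camera's direction were above 0. Of 6 measured aryl hydrocarbon receptor targets, NQO1 at -0.58 ± 0.02 and CYP1A1 at -0.35 ± 0.01 were lower and CYP1B1 at 0.40 ± 0.02 was higher (camera adjusted p = 0.668, 3 lower and 1 higher when adjusted over the list alone).

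Metabolic lists showed few changes. Of 19 cholesterol biosynthesis genes, the sterol enzyme genes SC5D at 0.62 ± 0.07 (SD, n = 2) and SQLE at 0.61 ± 0.11 and the sterol transport gene STARD4 at 0.41 ± 0.03 were higher and none was lower (camera adjusted p = 0.123, the same counts when adjusted over the list alone). Among 12 fatty acid synthesis genes, PNPLA3, a lipid droplet lipase gene, rose 2.79-fold (log2 1.48 ± 0.17) and the elongase gene ELOVL6 was lower at -0.72 ± 0.04 (camera adjusted p = 0.426, the same counts when adjusted over the list alone). Of 31 nuclear-encoded oxidative phosphorylation genes, COX6C at 0.65 ± 0.05 was higher and 4 were lower, among them COX5B at -0.50 ± 0.06, CYC1 at -0.45 ± 0.08 and SDHC at -0.40 ± 0.06 (camera adjusted p = 0.668, none in either direction when adjusted over the list alone).

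In the RNA interference machinery list, 2 of 15 genes were higher and 1 was lower (camera adjusted p = 0.431, the same counts when adjusted over the list alone). XPO5, the exporter of microRNA precursors, fell to 49.7% of mock (log2 -1.01 ± 0.06, SD, n = 2). TNRC6A at 0.44 ± 0.07 and the Argonaute gene AGO1 at 0.35 ± 0.05 were higher.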

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

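Of the tests of explanations in this part, only that of spots at 0 on 1 array was set before its result was seen; the others, and the reading of that test, were chosen after. Values without a single gene symbol, which the gene-level comparison leaves out, also carried signal. In the fit over 24139 single values, which was planned, 414 of 6733 such values passed limma's adjusted p, 198 higher and 216 lower. The lowest adjusted p in that limma fit was 0.0498, just under the threshold. Values with a single symbol that passed it numbered 941. Of these 6733, 884 moved at least 1.5-fold in the same direction on both arrays, against 30 in opposite directions.

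Lower ratios among genes expected to be silent in breast epithelium (median -0.26, or -0.20 on array 1 and -0.33 on array 2) are unusual, since MCF-7 cells should hold little of their RNA. Bias near the detection limit was probed with spots at exactly 0 on 1 array, whose median log2 ratio on the other array was 0.478 (bootstrap 95% interval 0.444 to 0.515, 1734 spots), opposite in sign to the list. The interval counts spots, and repeated spots often carry an identical value, so it may be too narrow. How near those spots lie to the limit was not measured, they are not the spots behind the list, and they were selected for having a ratio on the other array, so this bias stays open. The gene-level array medians were -0.02 and -0.03. Dye bias by probe also stays open without a dye swap, and no biological explanation was tested.

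Type I interferon response genes had a lower median than the silent genes on both arrays, by a gap of -0.53 on array 1 and -0.20 on array 2 (mean -0.36, SD 0.23). In 10000 random draws of 37 silent genes, 0 percent reached the interferon median of -0.59 over gene means, with a lowest draw of -0.53, and on array 2 alone 0.48 percent reached its median. The draws leave out the spread between arrays, and the gap stayed under 2 SD of that spread, so a shift shared with silent genes, whatever its source, stays open. An interferon response to the mock siRNA cannot be told apart from a loss of expression after CLOCK siRNA, since 0 arrays hold untransfected cells. Bias near the detection limit and an effect of CLOCK on these genes remain open.

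Clock genes that moved apart were set against a textbook division of the clock, applied after the values had been seen. As E-box-driven genes, direct targets of CLOCK and BMAL1, 11 measured genes were chosen, with a median of -0.39. Among them PER2 at 0.12 and CRY2 at 0.13 were above 0, and the other members were below 0. The list of 19 measured output genes fixed in advance, part of which was not chosen, had a median of -0.21. The REV-ERB proteins repress genes with ROR elements, and 5 genes were placed in that class, BMAL1, NPAS2, CRY1, NFIL3 and RORA. Their median was 0.57, the value of RORA itself. A difference of -0.96 or beyond arose in 0.02 percent of 10000 random pairs of lists from all genes. The split was made knowing the values. It placed CRY1 with the ROR-element genes although it is also a clock output, and RORA although it encodes an activator of BMAL1 transcription. This share is therefore no support. Loss of CLOCK activity at E-box genes therefore stays open as a hypothesis.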

How the results depend on the processing

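Alternatives on zeros and on the base of the logarithm were chosen after seeing the data. Centring, centring with scaling, robust moderation, pooled SD, the median of a gene's probes, leaving out silent genes and leaving out genes with any spot at 0 kept the number of changed genes between 2677 and 3696, within 1.5 times of 2953. Similar counts need not mean the same genes: with pooled SD, 2480 of the 3696 calls were shared with the main fit. Without moderation, changed, higher and lower genes numbered 1, 0 and 1, with 2739 at an unadjusted p under 0.05. The 1 gene was ARHGEF17, chosen after its values were seen, identical on both arrays at -0.16 and not passed in limma. Over single probes the calls numbered 1355, 606 and 749. These count values and not genes, and 414 of the 1355 had no single symbol. Changed, higher and lower genes numbered 307, 128 and 179 with a minimum change of 1.2-fold, and 5969, 2545 and 3424 at an adjusted p under 0.10. With exact zeros kept as values they numbered 0, 0 and 0 in limma (5562 at an unadjusted p under 0.05). Adding only the 3085 genes at 0 on both arrays to the measured genes also gave 0, 0 and 0 in limma (5627 at an unadjusted p under 0.05) and lowered the prior degrees of freedom from 1.90 to 0.450. With other zeros kept and those genes left out the prior was 1.69 and the numbers were 733, 306 and 427. With those genes counted as tested at p of 1, changed, higher and lower genes numbered 1972, 813 and 1159. The count of genes past 1.5-fold on both arrays was 333 at 2-fold, 2890 at 1.3-fold and 18 if values are log2 ratios, and 2133 to 2322 passed on a single array. Over single probes 2565 values passed, 884 of them without a single symbol. A single array leaves no test for counts of changed genes. CLOCK stayed near -2.73 in the settings in which it was followed with base 10 and both arrays. Among these it did not pass without moderation (adjusted p = 0.253) or with zeros kept (adjusted p = 0.0810). All 6 called lists lost their call with an estimated correlation (adjusted p = 0.844) and with fry, a test against no change (adjusted p = 0.120). Neither test called a simulated list shifted by 2.0 with 2 arrays, but there only 1 of 27 lists was shifted and its genes were independent. The silent list lost its call with zeros kept (adjusted p = 0.504). Other settings changed no list call. List medians moved by more than the spread between arrays in 8 of 27 lists with centring, 8 with scaling, 9 over single probes, 8 with zeros kept, 5 without genes with any spot at 0, 2 with medians, and 9 and 10 on each array alone. The array medians of 4 lists differed in sign, none of them called. Of 128 named genes, 119 were past the threshold and kept their direction throughout; BTRC (-0.07 on array 1, 0.02 on array 2) and TIMELESS (-0.03 and 0.06), which did not pass, turned when 1 array was left out. Of the 119, 119 lost their call without moderation and 119 with zeros kept, 84 with the 1.2-fold minimum, 5 with scaling, 4 with robust moderation, 2 with medians and 1 with centring; where not stated, the cause was not tested. Signal over background was not analysed here, so no limit is set for dim spots.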

Other observations

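All genes and families in this part were chosen after their values were seen. GAPDH, a glycolytic gene often used as a reference in RNA measurements, fell to 61.9% of mock (log2 -0.69 ± 0.09, SD, n = 2, limma adjusted p = 0.0348). It stayed lower when the arrays were centred (-0.67) and when they were centred and scaled (-0.67). Other common reference genes did not pass under any of these scalings. ACTB stood at -0.14, B2M at -0.19, HPRT1 at -0.06, PPIA at -0.16, YWHAZ at -0.12, GUSB at 0.07 and TBP at 0.29.

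Both bradykinin receptor genes were lower, BDKRB1 at 33.7% of mock (log2 -1.57 ± 0.01, SD, n = 2) and BDKRB2 at 48.5% (log2 -1.04 ± 0.10). UGT2B15 and UGT2B17, which encode enzymes that conjugate androgens, were higher, at 1.45 ± 0.11 and 1.75 ± 0.02. These UGT2B genes are close in sequence, so cross-hybridisation leaves their shares uncertain. All 4 genes had an adjusted p of 0.0324 in limma and kept their direction and call under both scalings.

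Gene families defined by the letters of their symbols were searched with Fisher's exact test in both directions, over 137 families of at least 12 measured members. Of 414 ZNF genes, which encode zinc finger proteins, 25 were lower and 52 were higher, with a median of 0.06. Fewer of them were lower than among other genes (adjusted p = 0.0124), and the excess of higher genes did not pass (adjusted p = 0.109). The deficit held after centring (23 lower, adjusted p = 0.0443) and did not pass after centring and scaling (22 lower, adjusted p = 0.0810). Of 34 KRT genes, keratins and their pseudogenes, 11 were lower and 2 were higher, with a median of -0.42, which did not pass (adjusted p = 0.109).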
